A study of Mus musculus with 6 samples.

How the data were processed

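Total RNA from 6 mouse livers at postnatal day 9 (3 wild type, 3 transgenic for liver-specific TFEB overexpression) was purified with Trizol and a silica column and labelled as biotinylated cRNA for Affymetrix GeneChip arrays, per the labels' protocols. The deposited values are log2 expression values per probe set that the authors made with affy and RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes, which give no versions. Further filters are not given in the sources used here. The deposited log2 table holds 22690 probe sets with 0 missing values and no detection calls. Because RMA gives all arrays nearly the same distribution, a change in total RNA per cell cannot be seen. The number of arrays limits the precision.

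Groups were taken from the sample titles, which call the arrays biological replicates. Probe sets were named from the platform annotation, which pairs 20380 probe sets with 1 gene, 691 with several and 1555 with none, and 64 are array controls. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, used for names only: 20351 probe sets matched, 29 kept the platform symbol and 0 symbols changed. No coordinates are given because the annotation names no build. Each of 12393 genes was represented by its probe set with the highest mean over all 6 arrays. Of 4956 genes with over 1 probe set, 102 had probe sets called in both directions.

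Transgenic and wild-type arrays were compared with limma 3.58.1 (lmFit and eBayes, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over all 12393 genes and a threshold of 0.05 on the adjusted p. A change of 2-fold is an absolute log2 fold change of 1. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so none was used for single genes. Gene lists were tested with limma's camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 28 lists, and again with an estimated correlation and with fry. Of 503 list members, 443 were measured; the others were not analysed here. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

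Genes named in the text follow a rule fixed with the lists, tests and most alternatives before the data were examined: Tfeb; the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, unnamed gene models passed over; and up to 4 members of each list past the threshold with the largest change, up to 2 in each direction first where members went both ways, or, where none passed, the 2 with the largest change, given as values only (Xist and Eif2s3y of the sex-linked list, a check of each animal). Genes outside this rule are marked where they appear. The alternatives were the mean of a gene's probe sets, every probe set on its own, leaving out probe sets whose suffix marks possible cross-hybridisation, leaving out the 40% of genes with the lowest mean, quantile normalization again, median centring, eBayes with trend and robust options, array weights, a replicate block and leaving out each array. Cyclic loess normalization, scaling to the bacterial hybridisation controls and counts of the list members that rose or fell under the alternatives were added after seeing the data, whereas list calls and medians with each array left out were fixed before.

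The scripts were tested on simulated data drawn around the real means and spreads of the transgenic against wild type comparison, with 200 of 12393 genes changed. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 55.2%, 91.0% and 100% of the changed genes, with 6 false calls among 12193 unchanged genes and 0 calls when no gene was changed. Camera called 0 lists when none was changed and 1 when 1 list was raised by 0.5. The simulated genes varied independently, whereas the estimated correlation of the real granulocyte list was 0.778 against the preset 0.01. The simulation therefore cannot show how often camera calls lists wrongly when their members vary together.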

Results

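The series compared liver RNA from 3 wild-type mice and 3 transgenic mice at postnatal day 9, with 1 array per animal. The transgenic mice carried a conditional allele for the transcription factor TFEB (gene Tfeb, formerly Tcfeb), which activates lysosomal and autophagy genes, and expressed Cre recombinase from the albumin promoter so that, per the labels, TFEB was overexpressed in liver only. The comparison asks how this overexpression changed liver gene expression. The labels call the arrays biological replicates. Values are log2 expression on the deposited scale, given as mean ± SD with n = 3 arrays per group, and differences are transgenic minus wild type with the standard error (SE) of the limma fit. The median over probe sets other than array controls was 6.74 to 6.76 on the wild-type arrays and 6.79 on each transgenic array. The small number of arrays limits the precision.

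Livers labelled transgenic and wild type differed in single genes by up to 6.28 on the log2 scale. Akr1c18, an aldo-keto reductase, fell by 4.23 (SE 0.15) and Tdo2, which begins hepatic tryptophan breakdown, fell by 3.58 (SE 0.16). Plet1, a surface protein of epithelial progenitors, rose by 6.28 (SE 0.18), and the lysosomal membrane glycoprotein gene Gpnmb rose by 5.09 (SE 0.24). Among gene lists fixed beforehand, those of cytochromes P450, bile acids, gluconeogenesis with the urea cycle, granulocytes and lymphoid cells were called lower. Those of the respiratory chain, YAP targets (5 of 9 genes) and red cell precursors were called higher. With an estimated correlation no list passed (smallest adjusted p = 0.239). The YAP and erythroid calls were lost without the 40% dimmest genes. Medians were then 0.80 for the 6 YAP and 0.77 for the 8 erythroid members left, against 0.46 and 0.56 for all measured members. Of 33 lysosomal enzyme and membrane protein genes, 9 were higher and 4 lower.

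Tfeb itself was not higher in the transgenic arrays. Its only probe set on the array read 6.71 ± 0.18 in wild type and 6.50 ± 0.13 in transgenic liver, a difference of -0.21 (SE 0.11, adjusted p = 0.168). The wild-type arrays read 6.91, 6.63 and 6.58 and the transgenic arrays 6.52, 6.61 and 6.36. The labels do not describe the construct, and a probe set outside the part that a transgene carries cannot show it, so this value does not check the labels. Groups are those of the labels throughout.

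Of 12393 genes tested with limma and Benjamini-Hochberg adjustment, 4990 (40.3%) passed an adjusted p of 0.05, with 2467 higher and 2523 lower in transgenic liver. A change of at least 2-fold was reached by 642 of them, 314 higher and 328 lower. The 3 values of each group did not overlap for 6661 genes (53.8%), against 10% by chance. Pearson's r across probe sets other than array controls, which are not independent replicates, was 0.994 to 0.997 within groups and 0.977 to 0.979 between them. Bacterial RNAs spiked into every sample read lower in the transgenic arrays. All 14 probe sets for the hybridisation controls bioB, bioC and bioD were lower in every transgenic array than in any wild-type array, with a median difference of -0.37. With genes ordered by mean brightness into 10 groups, the median difference was lowest in a dim group at -0.16 and highest in a bright group at 0.09. With arrays scaled to those hybridisation controls, an alternative chosen after seeing the data, the median of all genes moved from -0.04 to 0.34, and 6997 genes were higher and 633 lower (91.7% of calls higher against 49.4%). Directions below are relative to the scale as deposited.

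**Figure D1:**
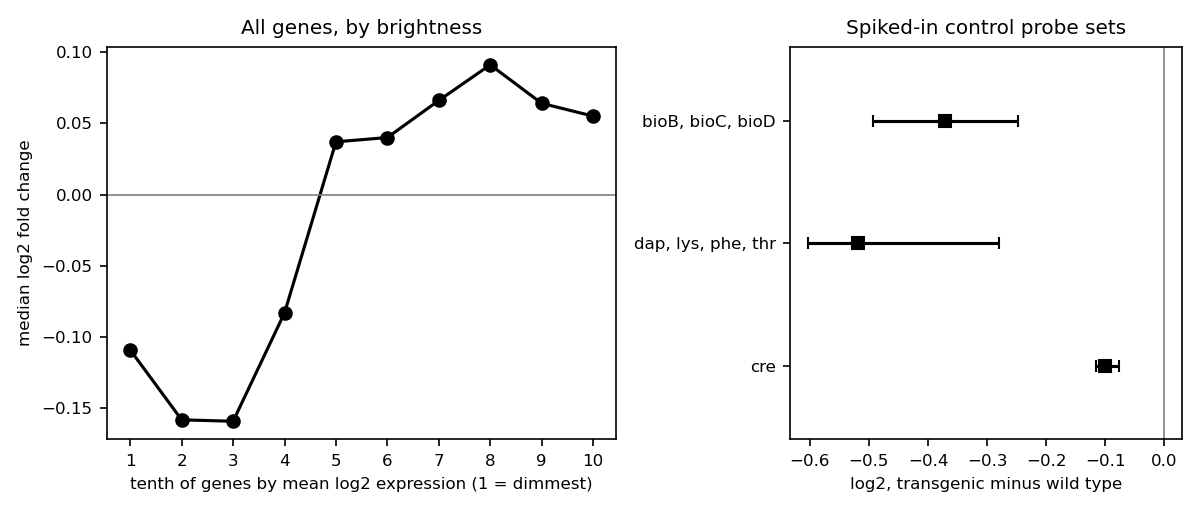
Left, the median log2 fold change (transgenic minus wild type) of 10 groups of genes ordered by mean log2 expression, lowest at -0.16 and highest at 0.09. Right, squares give the median log2 difference of each class of spiked-in control probe sets and bars their lowest and highest value, with medians of -0.37 for bioB, bioC and bioD, -0.52 for dap, lys, phe and thr, and -0.10 for cre. Only 1 of the 4 cre probe sets was lower in every transgenic array than in any wild-type array. The transgenic mice expressed Cre recombinase, so these sets may not read the spiked-in RNA alone, which was not tested.

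Sex-linked transcripts, a fixed list used as a check of each animal and not tested as a set, differed between animals. Xist, expressed from the inactive X chromosome, read 13.03 to 13.19 in 5 arrays and 5.58 in transgenic replicate 1, where the Y-linked gene Eif2s3y read 9.32 against 3.06 to 3.43 elsewhere. The transgenic group thus held 1 array with a male pattern and the wild-type group none. Without that array 2095 genes were higher and 2067 lower, and 639 of the 642 genes changed at least 2-fold were still called in the same direction.

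Among the 10 largest rises, Plet1 went from 5.52 ± 0.34, a dim reading with unknown signal over background, to 11.80 ± 0.22 (adjusted p = 2e-06), although only 1 of its 2 probe sets was called. Gpnmb rose from 5.49 ± 0.30 to 10.58 ± 0.46 (adjusted p = 1.02e-05). Slpi, a secreted protease inhibitor, rose from 8.24 ± 0.07 to 13.27 ± 0.22 (32.7-fold), and Nupr1, a stress-induced chromatin protein, from 7.22 ± 0.16 to 12.14 ± 0.18 (30.4-fold). Cldn4, a tight junction protein, rose by 4.61 (SE 0.27) and the ectonucleotidase gene Entpd2 by 4.52 (SE 0.13). The secreted glutathione peroxidase gene Gpx3 rose by 4.46, the WNT ligand gene Wnt4 by 4.44, the fatty acid binding protein gene Fabp3 by 4.28 and the beta-tubulin gene Tubb2b also by 4.28.

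Among the 10 largest falls, Akr1c18 went from 10.93 ± 0.30 to 6.71 ± 0.14 (adjusted p = 2.85e-06). Ugt3a2, a glycosyltransferase, fell by 3.75 (SE 0.24), and Tdo2 went from 11.69 ± 0.05 to 8.11 ± 0.36. Akr1c20 fell by 3.37, Cyp2c54 fell by 3.32, the sulfotransferase gene Sult2a2 fell by 3.21 and the steroid dehydrogenase gene Hsd17b6 fell by 3.11, the last with 1 of 2 probe sets called. Pnliprp1, a pancreatic lipase relative, fell by 3.20 and the chitinase-like gene Chil3 fell by 3.08 (SE 0.45, adjusted p = 0.00146). Dio1, which activates thyroid hormone, fell by 2.97 (SE 0.15). Probes for the Akr1c, Cyp2c, Sult2a and Ugt families can bind transcripts of close relatives, so the family member is uncertain.

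**Figure D2:**
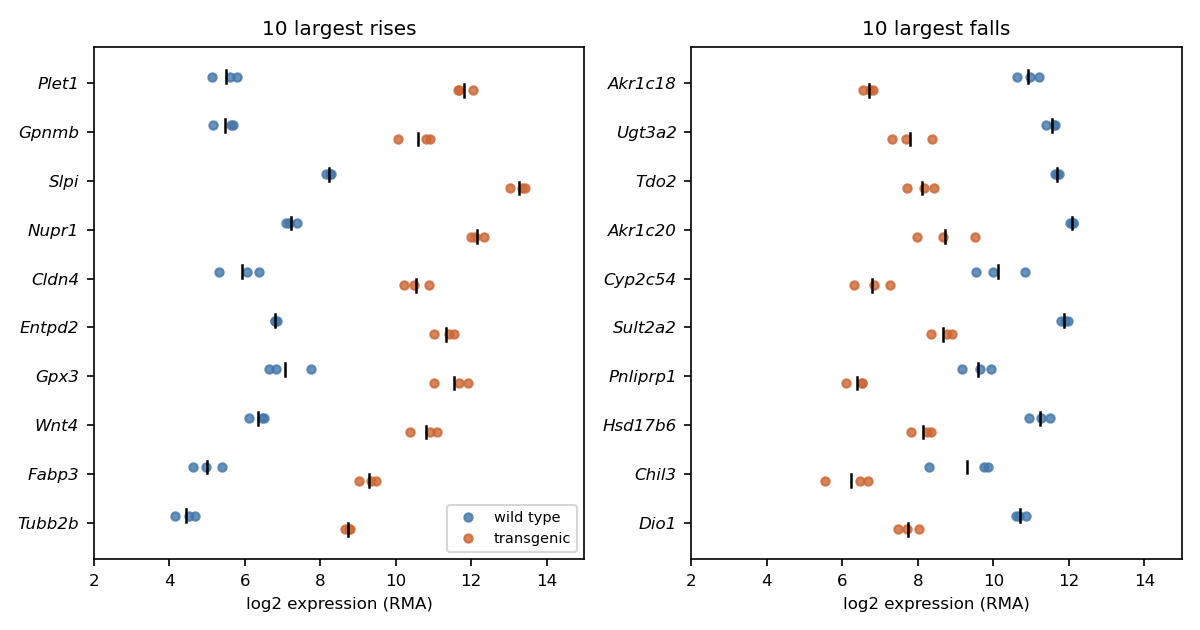
Log2 expression of the 10 genes with the largest rise and the 10 with the largest fall, 1 point per array (3 wild type, 3 transgenic), with a black line at each group mean. The groups do not overlap for any of the 20 genes, and Plet1 runs from a wild-type mean of 5.52 to a transgenic mean of 11.80.

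Of 28 gene lists fixed before the data were examined, 16 differed from the other genes by limma's camera test at its preset correlation, 8 upward and 8 downward. Other splits of the arrays, which mixed the groups, gave 6 to 15 lists by the same test. With a correlation estimated from the arrays no list passed, the smallest adjusted p being 0.239. Calls were also lost where the estimate lay below the preset 0.01, for the hepatocyte (-0.067), acinar (-0.084) and YAP (-0.1) lists. The loss of those calls thus does not show that their members varied together. By fry, which does not compare a list with other genes, 18 lists moved on balance in 1 direction and 27 changed in either direction. Leaving out the 40% of genes with the lowest mean ended the calls of the vacuolar ATPase, cell cycle, WNT, YAP, ER stress, NRF2, cholangiocyte and erythroid lists, and scaling to the bacterial controls those of the ER stress, NRF2 and cholangiocyte lists. Without the dimmest genes the median of all genes moved from -0.04 to 0.06, while the list medians were 0.26 for the vacuolar ATPase (0.26 with all genes), 0.27 for the cell cycle (0.27), -0.65 for WNT (-0.61), 0.13 for ER stress (0.15), 0.21 for NRF2 (0.11) and 0.92 for cholangiocytes (0.39). These medians cover only the members left, 14, 24, 8, 15, 14 and 12 in that order, fewer than in each full list. With scaling to the bacterial controls, which moved the median of all genes to 0.34, the members higher and lower were 17 and 1 for autophagy, 9 and 3 for fatty acid oxidation, 9 and 3 for lipogenesis, and 12 and 0 for cholesterol synthesis. They were 5 and 4 for WNT, 6 and 0 for Notch, 9 and 2 for fetal genes and 10 and 1 for cholangiocytes. ER stress had 12 and 1, NRF2 had 13 and 2, acute phase had 7 and 0 and stellate genes had 14 and 1. Bile acids had 3 and 9, cytochromes P450 had 1 and 10, and gluconeogenesis with the urea cycle had 1 and 7. Hepatocytes had 2 and 6 and acinar genes had 1 and 3. No gene was in more than 1 list.

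**Figure D3:**
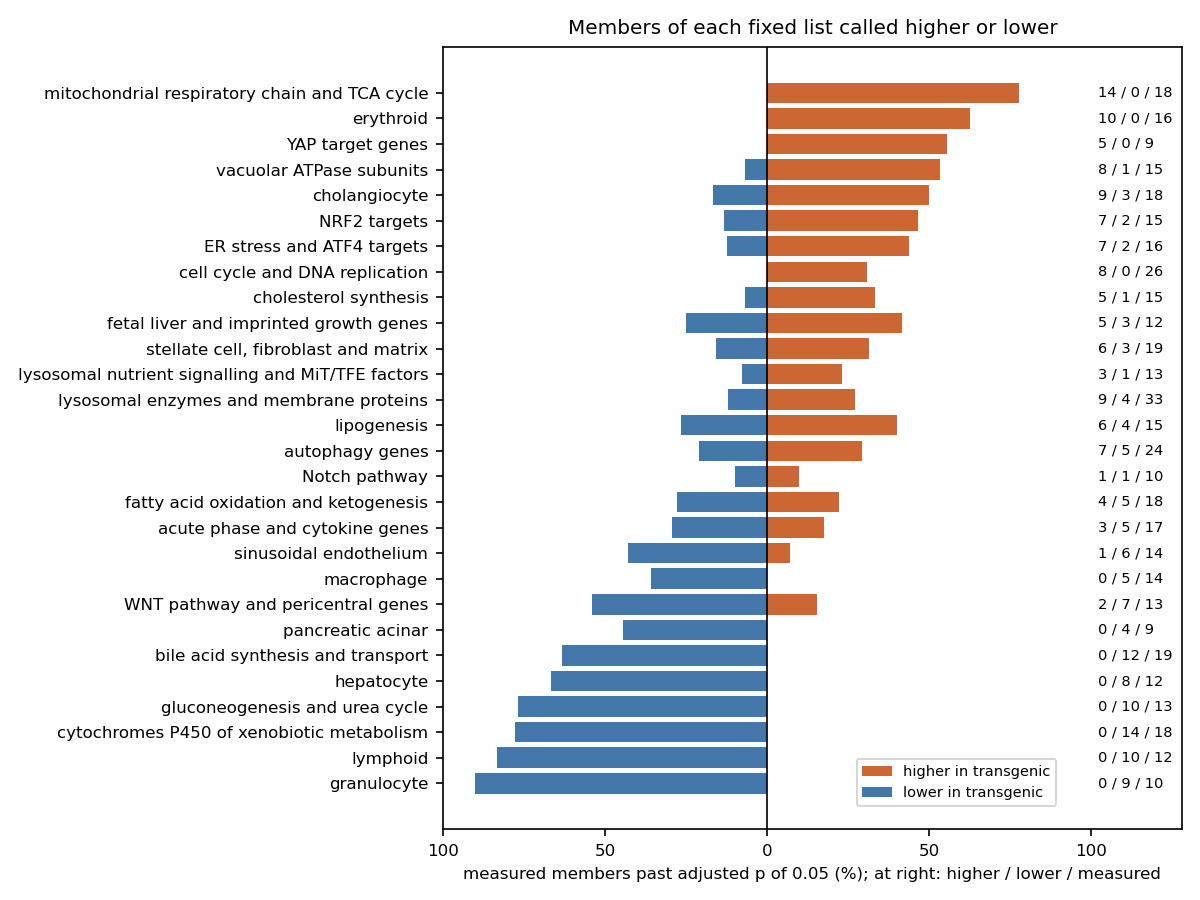
Percent of the measured members of each of the 28 fixed lists called higher (orange, right) or lower (blue, left) in transgenic liver at an adjusted p of 0.05, with the numbers higher, lower and measured at the right. Granulocyte genes have the largest share lower (9 of 10) and respiratory chain and TCA cycle genes the largest share higher (14 of 18).

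Lysosomal enzyme and membrane protein genes moved in both directions. Of 33 measured, 9 rose, 4 fell and 20 did not pass (9 and 5 adjusted over the list alone). Gla, the alpha-galactosidase, rose by 1.54 (SE 0.10) and Ctsl, a cathepsin, by 0.99 (SE 0.08), while Ctsh fell by 0.56 and Fuca1 fell by 0.37. The others past the threshold, named after their values were seen, were Cln3 (0.91), Galns (0.77), Ctsd (0.52), Manba (0.47), Npc2 (0.43), Gusb (0.30), Ctsb (0.24), Ctsf (-0.31) and Scarb2 (-0.30), and without transgenic replicate 2 only 2 genes fell. The list was not called (adjusted p = 0.0603), but it was called up without wild-type replicate 1 (0.0404), transgenic replicate 1 (0.0386) or transgenic replicate 2 (0.0453), and with arrays scaled to the bacterial controls (0.0385), when 27 rose and 0 fell. The range across alternatives was 0.0385 to 0.38. Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, rose for 8 of 15 members, with 1 lower and 6 not passed (10 and 1 adjusted over the list alone). Atp6v0e rose by 0.84, Atp6v1a by 0.73 and Atp6v0a1 by 0.48, the last with 1 of its 4 probe sets called lower, and Atp6v0a2 fell by 0.27, a change that had the opposite sign (0.05) over the mean of its probe sets. The list was called up (adjusted p = 0.0025, and adjusted p = 0.239 with an estimated correlation), and not without the 40% dimmest genes (adjusted p = 0.0698, over a range of 0.000747 to 0.0698 across alternatives). Single calls were lost without transgenic replicate 2 for Fuca1 (adjusted p = 0.0555), and for Atp6v0a2 without transgenic replicate 1 (0.0501), 2 (0.0507) or 3 (0.0705). The count of subunits that rose was 5 without wild-type replicate 2, without transgenic replicate 2 or without transgenic replicate 3.

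Of 24 autophagy genes, 7 rose, 5 fell and 12 did not pass, with the same counts adjusted over the list alone. Gabarapl1, a ubiquitin-like autophagosome protein, rose by 1.52 (SE 0.19) and the cargo receptor gene Sqstm1 by 0.94 (SE 0.07), while Ulk2, an initiating kinase, fell by 0.86 and Atg3 fell by 0.56. Wipi1 (0.38), Tax1bp1 (0.37), Gabarapl2 (0.28), Map1lc3b (0.23), Becn1 (0.21), Atg16l1 (-0.43), Atg5 (-0.39) and Uvrag (-0.32), named after their values were seen, made up the rest, and the list was not called (adjusted p = 0.347). Among 13 genes of lysosomal nutrient signalling and the TFEB family, 3 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone. Besides Gpnmb, Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 3.02 (SE 0.20) on all 5 of its probe sets, Rragc rose by 0.23 and Lamtor2 fell by 0.30. Rragc lost its call without wild-type replicate 1 (adjusted p = 0.0522), 2 (0.0699) or 3 (0.0777) and without transgenic replicate 2 (0.1) or 3 (0.0927), and also with quantile normalization again, median centring and cyclic loess (0.155). That list was not called either (adjusted p = 0.0699), but it was called up without transgenic replicate 1 (0.0414) or transgenic replicate 2 (0.0458), and with arrays scaled to the bacterial controls (0.04), when 11 rose and 0 fell. Its range across alternatives was 0.04 to 0.23.

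Of 18 cytochromes P450 of xenobiotic metabolism, 14 fell, 0 rose and 4 did not pass (15 fell adjusted over the list alone), with a median difference of -0.99. Cyp2c37 fell by 2.89 (SE 0.16), Cyp2j5 fell by 2.77, Cyp2b9 fell by 2.62 and Cyp2c29 fell by 2.50. The list was called down (adjusted p = 1.28e-07), with adjusted p = 0.239 with an estimated correlation. Bile acid synthesis and transport genes fell for 12 of 19 members, 0 rose and 7 did not pass, with the same counts adjusted over the list alone. Akr1d1, a reductase of bile acid synthesis, fell by 2.34 (SE 0.11), the uptake transporter gene Slco1b2 fell by 2.04, Slc27a5 fell by 1.71 and the nuclear receptor gene Nr0b2 fell by 1.59. Camera called the list down (adjusted p = 1.85e-05, and adjusted p = 0.239 with an estimated correlation).

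In gluconeogenesis and the urea cycle, 10 of 13 genes fell, 0 rose and 3 did not pass (12 fell adjusted over the list alone). Pcx, pyruvate carboxylase, fell by 1.34 (SE 0.10), Pck1 fell by 1.06 (SE 0.24), Nags fell by 1.01 and Tat fell by 0.99. This set was called down (adjusted p = 0.00026, and adjusted p = 0.283 with an estimated correlation). Hepatocyte markers fell for 8 of 12 members, with 0 higher, 4 not passed and the same counts adjusted over the list alone. Besides Tdo2, the apolipoprotein gene Apoc3 fell by 1.44, Hpd fell by 1.09 and the clotting factor gene F9 fell by 1.07. As a set these genes were called down (adjusted p = 0.000416, and adjusted p = 0.239 with an estimated correlation). Alb and Ttr, named after their values were seen, did not pass the threshold, with Alb at 14.87 ± 0.03 in wild-type and 14.87 ± 0.01 in transgenic liver and Ttr at 14.79 ± 0.03 and 14.75 ± 0.03, close to the highest value on each array, where differences are hard to see.

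Mitochondrial respiratory chain and TCA cycle genes rose for 14 of 18 members, with 0 lower, 4 not passed and the same counts adjusted over the list alone. Idh3a, a TCA cycle dehydrogenase subunit, rose by 1.16 (SE 0.09), the nuclear receptor gene Esrra by 0.82, the cytochrome c gene Cycs by 0.72 and Ndufv1 by 0.55. Camera called the list up (adjusted p = 9.78e-06, and adjusted p = 0.283 with an estimated correlation). Fatty acid oxidation and ketogenesis genes split, with 4 of 18 higher, 5 lower and 9 not passed (5 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.5, median -0.11 and mean 0.15, of opposite sign). Acot1, an acyl-CoA thioesterase, rose by 3.66 (SE 0.17) and Pdk4 rose 2.29-fold, while the nuclear receptor gene Ppara fell by 1.09 and Bdh1 fell by 0.74. The remaining members past the threshold, named after their values were seen, were Vnn1 (1.14), Plin2 (0.66), Acaa2 (-0.72), Cyp4a14 (-0.42) and Slc25a20 (-0.36).

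Lipogenesis genes also split, with 6 of 15 higher, 4 lower and 5 not passed, the same adjusted over the list alone (adjusted p = 0.505). Me1, malic enzyme, rose by 1.48 (SE 0.07) and Elovl6 by 1.47, while Elovl5 fell by 1.40 and Srebf1, the transcription factor of the pathway, fell by 1.24. Acacb (1.14), Acly (0.41), Gpam (0.33), Dgat2 (0.29), Mlxipl (-0.84) and Thrsp (-0.42), named after their values were seen, completed the counts. Of 15 cholesterol synthesis genes, 5 rose, 1 fell and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.0504). Fdps rose by 1.49 (SE 0.19), Sqle by 0.88 and Mvd by 0.75, and Sc5d fell by 0.30, a call lost without wild-type replicate 1 (adjusted p = 0.075), 2 (0.124) or 3 (0.0723) and without transgenic replicate 1 (0.076) or 3 (0.107). Lss (0.60) and Nsdhl (0.55) completed the 5 and were named after their values were seen. The list was called up without wild-type replicate 2 (adjusted p = 0.0047) or transgenic replicate 3 (0.0152), with the mean of a gene's probe sets (0.037) and with median centring (0.0452), over a range of 0.0047 to 0.267 across alternatives. The number that rose was 8 without wild-type replicate 2 and 3 without transgenic replicate 2, when 2 fell.

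Of 13 WNT pathway and pericentral genes, 2 rose, 7 fell and 4 did not pass (2 and 8 adjusted over the list alone). Lgr5, a WNT target and receptor, fell by 2.27 (SE 0.08) and Tbx3 fell by 1.83, the latter with 1 of its 2 probe sets called, while Oat, an ornithine aminotransferase, rose by 2.21 and Myc by 1.97. The set test called the list down (adjusted p = 0.0379, and adjusted p = 0.422 with an estimated correlation), and not without wild-type replicate 3 (adjusted p = 0.0677), with the mean of a gene's probe sets (0.0615) or with median centring (0.0586), over a range of 8.4e-05 to 0.179 across alternatives. YAP target genes rose for 5 of 9 members, with 0 lower, 4 not passed and the same counts adjusted over the list alone. Ankrd1 rose by 3.22 (SE 0.13), Ccn1 by 2.18, Ajuba by 1.31 and Ccn2 by 1.13, and Amotl2 (0.46), named after its value was seen, was the fifth. As a set these genes were called up (adjusted p = 0.0131, and adjusted p = 0.239 with an estimated correlation). In the Notch pathway 1 of 10 genes rose (Jag1, 0.76), 1 fell (Notch1, -0.48) and 8 did not pass, the same adjusted over the list alone (adjusted p = 0.724).

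Cholangiocyte markers rose for 9 of 18 members, while 3 fell and 6 did not pass, with the same counts adjusted over the list alone. Besides Cldn4, Cldn7 rose by 3.56 (SE 0.40), and Sox9 (2.22) and Epcam (1.94), named after their values were seen, rose as well. Prom1 fell by 1.89 (SE 0.13) and Ehf fell by 0.54, the latter not called without wild-type replicate 1 (adjusted p = 0.106) or 2 (0.114), without transgenic replicate 1 (0.122) or 3 (0.111), or with cyclic loess (0.0931). In addition, Pkhd1 (-0.41) and Krt19 (-0.27, adjusted p = 0.608), both named after their values were seen, gave 1 more fall and 1 value short of the threshold. The set test called the list up (adjusted p = 0.0255, and adjusted p = 0.559 with an estimated correlation), and not without wild-type replicate 3 (adjusted p = 0.08, over a range of 0.00188 to 0.457 across alternatives). The number that fell was 1 without wild-type replicate 1, without wild-type replicate 2 or without transgenic replicate 3, and 5 without wild-type replicate 3.

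Of 12 fetal liver and imprinted growth genes, 5 rose, 3 fell and 4 did not pass, the same adjusted over the list alone (adjusted p = 0.283). Dlk1 rose by 1.07 (SE 0.26; adjusted p = 0.0524 without transgenic replicate 3) and Peg3 by 1.01, while Cyp3a16 fell by 1.45 and Cdkn1c, a cell cycle inhibitor, fell by 1.12. Igf2bp1 (0.71), Hmga2 (0.51), Afp (0.35) and Igf2 (-0.27), named after their values were seen, made up the rest. Cell cycle and DNA replication genes rose for 8 of 26 members, with 0 lower and 18 not passed (6 rose adjusted over the list alone). Cenpe rose by 0.60, Cdc20 by 0.53, Mcm7 by 0.49 and Bub1 by 0.46. Bub1 lost its call without wild-type replicate 2 (adjusted p = 0.0723) or transgenic replicate 1 (0.119), 2 (0.0975) or 3 (0.0742), and also with quantile normalization again, median centring and cyclic loess (0.0913). By camera the list was called up (adjusted p = 0.00117, and adjusted p = 0.589 with an estimated correlation). Markers of erythroid cells were higher as well (10 of 16, with a median of 0.56). The number of cell cycle genes that rose was 3 without transgenic replicate 1 (the array with the male pattern), transgenic replicate 2 or wild-type replicate 2. It was 15 without wild-type replicate 3.

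Stress-response lists held large changes in a few members. Among 16 ER stress and ATF4 targets, 7 rose, 2 fell and 7 did not pass, the same adjusted over the list alone. Trib3, a pseudokinase, rose by 2.07 (SE 0.15) and Psat1, of serine synthesis, by 1.98, while Herpud1 fell by 0.71 and Pdia4 fell by 0.26. Pdia4 lost its call without wild-type replicate 1 (adjusted p = 0.0703) or 2 (0.0687) and without transgenic replicate 2 (0.0686) or 3 (0.0962). This set was called up (adjusted p = 0.022, and adjusted p = 0.283 with an estimated correlation), but not with cyclic loess normalization, an alternative chosen after seeing the data (adjusted p = 0.0623, over a range of 0.0114 to 0.206 across alternatives). A single fall was left without wild-type replicate 1 or 2, or without transgenic replicate 2 or 3. Among 15 NRF2 targets, 7 rose, 2 fell and 6 did not pass, the same adjusted over the list alone. Gsta2, a glutathione transferase whose probes can bind close relatives, rose by 2.92 (SE 0.33) and Ugdh by 1.85, while Gsta4 fell by 0.75 and Gclc fell by 0.66. The genes were called up as a list (adjusted p = 0.021, and adjusted p = 0.327 with an estimated correlation). Of 17 acute phase and cytokine genes, 3 rose, 5 fell and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.981). The iron hormone gene Hamp rose by 3.54 (SE 0.33) and the chemokine gene Ccl2 by 2.40, while the fibrinogen genes Fgb (-0.57) and Fga (-0.56) fell. Socs3 (0.66), Saa3 (-0.53), Hp (-0.44) and Fgg (-0.37), named after their values were seen, made up the rest.

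Blood cell markers moved apart. Granulocyte genes fell for 9 of 10 members, with 0 higher, 1 not passed and the same counts adjusted over the list alone. Camp fell by 2.78 (SE 0.37), Ngp fell by 2.67, Ltf fell by 2.64 and S100a9 fell by 2.00. Wild-type replicate 1 read lower than the other wild-type arrays, at 10.36 for Camp against 11.37 and 11.63 and at 6.66 for the lymphoid gene Vpreb1 against 8.15 and 8.45. That array also had the largest 3′ minus 5′ log2 difference of the array's control probe sets, 1.01 for Gapdh against 0.54 to 0.73 elsewhere and 1.97 for actin against 1.63 to 1.86. Without it 9 granulocyte and 10 lymphoid genes still fell, with medians of -2.20 and -0.98. By camera the list was called down (adjusted p = 0.000416, and adjusted p = 0.422 with an estimated correlation). Lymphoid genes fell for 10 of 12 members, with 0 higher and 2 not passed (11 fell adjusted over the list alone). The B cell precursor genes Vpreb1 (-2.55) and Igll1 (-2.03) fell, as did the granzyme gene Gzma (-1.86) and Cd79b (-1.55). Igll1 is uncertain, since 1 of its 2 probe sets was called and the other differed by 0.03. The genes were called down as a list (adjusted p = 0.000179, and adjusted p = 0.283 with an estimated correlation). Erythroid genes rose for 10 of 16 members, with 0 lower and 6 not passed (11 rose adjusted over the list alone). Car1 rose by 1.06 (SE 0.16), Rhag by 1.02, Slc4a1 by 1.00 and Epb42 by 0.98. Taken as a set, they were called up (adjusted p = 0.00181, and adjusted p = 0.376 with an estimated correlation).

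**Figure D4:**
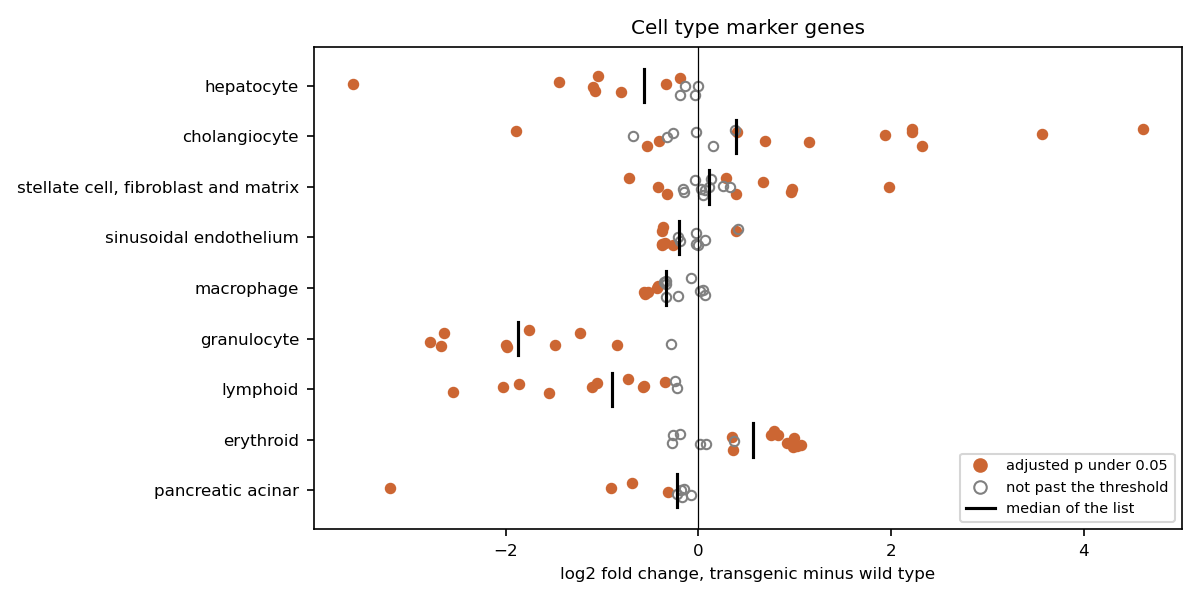
Log2 fold change (transgenic minus wild type) of each measured marker gene of 9 cell types, 1 point per gene, filled where the adjusted p was under 0.05, with a black line at the median of the list. Medians run from -1.87 for granulocyte to 0.56 for erythroid markers, and cholangiocyte markers spread from -1.89 (Prom1) to 4.61 (Cldn4).

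Of 14 macrophage markers, 5 fell, 0 rose and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.0504). Adgre1 (-0.56), Marco (-0.56), Aif1 (-0.52) and C1qa (-0.43) fell, and C1qc (-0.42) was named after its value was seen. Adgre1 lost its call without wild-type replicate 2 (adjusted p = 0.106) or 3 (0.0975) or transgenic replicate 1 (0.0872) or 2 (0.104). Marco lost it without wild-type replicate 2 (adjusted p = 0.0972) or 3 (0.0999), without transgenic replicate 2 (0.106) or 3 (0.0737) and with trend and robust options (0.0503), and Aif1 without wild-type replicate 3 (0.0513). The list was called down without wild-type replicate 1 (adjusted p = 0.00374), transgenic replicate 1 (0.0449) or transgenic replicate 3 (0.014), without the 40% dimmest genes (0.0308), with quantile normalization again (0.0255), trend and robust options (0.0367) or array weights (0.0133), and with cyclic loess (0.0128) or scaling to the bacterial controls (0.0174). Across alternatives its range was 0.00374 to 0.158. The number that fell was 9 without wild-type replicate 1, 2 without wild-type replicate 2, 1 without wild-type replicate 3, 3 without transgenic replicate 1 and 2 without transgenic replicate 2. Sinusoidal endothelial markers fell for 6 of 14 members, with 1 higher and 7 not passed (7 and 1 adjusted over the list alone; adjusted p = 0.133). Cdh5 (-0.38), Kdr (-0.38) and Tek (-0.37) fell, Lyve1 rose by 0.40, and Flt1 (-0.36), Stab2 (-0.34) and Oit3 (-0.27) were named after their values were seen. Lyve1 lost its call without wild-type replicate 1 (adjusted p = 0.0511) or 3 (0.072), without transgenic replicate 1 (0.0706) or 2 (0.0676) and with cyclic loess (0.0669). With cyclic loess the list was called down (adjusted p = 0.0481, over a range of 0.0481 to 0.411 across alternatives). Stellate cell, fibroblast and matrix markers rose for 6 of 19 members and fell for 3, with 10 not passed, the same adjusted over the list alone (adjusted p = 0.199). Timp1 rose by 1.98 (SE 0.20) and Tagln by 0.97, while Lrat fell by 0.72 and Postn fell by 0.42. Postn lost its call without wild-type replicate 2 (adjusted p = 0.099) or 3 (0.0915) or transgenic replicate 1 (0.0557), 2 (0.0991) or 3 (0.0618). In the same list, Acta2 (0.96), Vim (0.67), Sparc (0.39), Col4a1 (0.29) and Dcn (-0.32) were named after their values were seen. Without transgenic replicate 2 the list held 3 rises and 1 fall, and 1 fall was left without wild-type replicate 2, wild-type replicate 3 or transgenic replicate 3. Pancreatic acinar genes fell for 4 of 9 members, with 0 higher, 5 not passed and the same counts adjusted over the list alone. Besides Pnliprp1, Cela2a fell by 0.90, Cela1 fell by 0.69 and Prss2 fell by 0.32. Camera called these genes down (adjusted p = 0.00745, and adjusted p = 0.239 with an estimated correlation). With arrays scaled to the bacterial controls, the acinar median was 0.16, below the median of all genes at 0.34, and 0 macrophage and 0 endothelial markers fell while 3 and 6 rose.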

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

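Of the tests in this part, those of the other splits of the arrays (for gene counts), of the sex of 1 animal, of the poly-A step, of the share of bile duct cells and of dilution were chosen only after the result was seen, as were cyclic loess normalization and scaling to bacterial controls.

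Outside the main comparison, probe sets with no gene or several genes gave signal too, with 283 of 2246 called higher in transgenic arrays and 32 of them at least 2-fold higher, while 319 were lower, 45 of them at least 2-fold. The array's own Gapdh 3′ control probe set, not used in the gene test, was 0.56 higher in transgenic arrays (0.555, from 12.42 ± 0.08 to 12.97 ± 0.13, n = 3 each), its middle and 5′ sets were 0.70 and 0.72 higher, and the 3 actin sets 0.31 to 0.37 higher.

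The real split of the arrays gave 4990 changed genes and 642 changed at least 2-fold, and the highest of the other splits gave 0 of either with limma, so 1 of the 10 splits was as large, the real one, with at most 403 genes in another split at an unadjusted p under 0.05 against 6180 for the real split. For gene lists the real split called 16 and the highest other 15, again 1 of 10. The other splits called 6 to 15 lists, each with 0 genes called. Camera at its preset correlation thus called lists also where the groups were mixed. Splits of 3 against 3 are too few for a share under 0.05. Every other split also mixed the groups, so the difference between groups added to the spread within each side. Few gene calls were therefore likely beforehand, and the 0 calls and 403 genes do not measure what chance gives.

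The first pattern is a shift of whole arrays: dim genes were lower and bacterial controls were lower in the transgenic group. A difference in the poly-A control step alone is argued against by the hybridisation controls, added after labelling, whose median difference was -0.371. The brightness shift was small, with medians of -0.16 to 0.09 over groups of genes ordered by brightness, against changes of at least 1. It is thus too small on average to give changes of at least 2-fold. With cyclic loess normalization 100% of the 642 kept call and direction and 611 were still at least 2-fold. That result was nearly fixed by the size of the shift and adds no support of its own. Without transgenic replicate 1 only arrays with a female pattern remained, and 99.53% of the 642 kept call and direction. Sex thus does not account for those calls. A gene changed in that animal alone would rarely be called, as Xist and Eif2s3y were not, so this high share was likely beforehand. For the 1014 of 4957 dim genes called lower, 51.68% (524) kept the call with cyclic loess, between the values that would have favoured or excluded a brightness shift, so for these genes a shift and a genotype effect cannot be told apart. More labelled RNA on the transgenic arrays and a larger mRNA pool in transgenic liver stay open as untested hypotheses. The labels name no processing batch, so a batch that followed the groups could not be told apart from the genotype.

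The second pattern is the rise of cholangiocyte genes without all of them. A larger share of ordinary bile duct cells would raise the markers about alike. Instead 3 markers were called lower, but only 1 under some alternatives (1 to 5 over all of them), so that count alone does not decide. A second test took the 15 markers with a wild-type mean under 9, with limits set after the values were seen. The 95% interval of 7 lay wholly below a rise of 1, including Krt19 (wild-type mean 7.05, -1.17 to 0.638) and Pkhd1 (8.09, -0.725 to -0.1). The 9 markers called higher had a median of 2.21. The 15 markers thus did not rise alike. Because the limits were set after the values were seen, this test does not decide on a larger share of ordinary duct cells. Several of the 7 were also dim in wild type, such as Ehf (4.03) and Tspan8 (5.38), with unknown signal over background. For the markers that rose, a larger share and a change within cells cannot be told apart. Without transgenic replicate 1, which left only arrays with a female pattern, 8 markers were still higher, so those 8 do not rest on its sex. A change of expression within hepatocytes or an altered duct cell stays open as an untested hypothesis, as does the genotype.

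The third pattern is the fall of granulocyte and lymphoid genes. Dilution of all blood and non-parenchymal cells is argued against by erythroid genes, which it would lower and whose median was 0.562 (10 of 16 rose, 0 fell). Without the 40% dimmest genes their median was 0.77 over the 8 members left (6 rose, 0 fell), although the list's call was then lost (adjusted p = 0.0572, range 0.000356 to 0.0572). The macrophage (-0.336) and endothelial (-0.201) medians went the way of dilution. The stellate, fibroblast and matrix median (0.115, 6 rose and 3 fell) did not. A loss of some of these cell types that spares erythroid cells stays open. The median of the 22 granulocyte and lymphoid members was -1.36 as deposited and -1.377 with cyclic loess. It lay far beyond the brightness shift, whose medians over groups of genes ran from -0.16 to 0.09. That shift is thus too small to account for the fall, and the median kept with cyclic loess adds no further support. Fewer of these cells in transgenic liver, or a difference in blood left in the organ by cell type, stays open and was not tested.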

How the results depend on the processing

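The fits compared 3 arrays with 3, and with no detection calls the signal over background of dim genes is unknown. Cyclic loess and scaling to the bacterial hybridisation controls were chosen after seeing the data. With 1 array left out, 3780 to 4818 genes changed (1876 to 2411 higher, 1890 to 2407 lower), 614 to 659 at least 2-fold (304 to 326 higher, 310 to 339 lower), and 14 to 19 lists were called. Every probe set on its own gave 8006 calls (4087 higher, 3919 lower), 966 at least 2-fold (493 higher), because more units were tested. Without the 40% dimmest genes 1660 were lower and 9 lists were called, 8 of them among the 16, and with an estimated correlation 0 lists. Scaling to the bacterial controls, which moved the median of all genes to 0.34, gave 7630 calls (6997 higher, 633 lower) and 744 and 186 at least 2-fold, and Tfeb read 0.17. It turned Fuca1 (0.0084), Atp6v0a2 (0.11), Lamtor2 (0.083), Sc5d (0.077), Pdia4 (0.11), Cdh5 (2e-04), Kdr (7e-04), Tek (0.006), Prss2 (0.062) and the medians of the pancreatic acinar (0.16), macrophage (0.042), endothelial (0.178), fatty acid oxidation (0.269) and Notch (0.327) lists positive, none above that median. Atp6v0a2 read 0.049 with the mean of its probe sets and Igll1 0.031 without cross-hybridising probe sets; the cause was not tested. Of 2000 values of the other 126 named genes under alternatives, 1912 kept direction and side of the threshold, 77 lost the call, 0 gained it and 11 reversed. With scaling to the bacterial controls Adgre1, Aif1, Atg3, C1qa, Ctsh, Ehf, Fga, Fgb, Marco, Notch1 and Postn lost the call, with the mean of a gene's probe sets Cdh5, Lyve1, Pdia4 and Sc5d, with array weights Ehf, with quantile normalization again Bub1, Ehf, Rragc and Sc5d, and without cross-hybridising probe sets Mvd.

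With the replicate block 4279 genes were called, 2111 higher and 2168 lower, all 16 lists kept their call and 2 more passed, cholesterol synthesis (adjusted p = 0.0335) and macrophage (0.0257). Bub1, Marco, Postn and Rragc lost the call. Same-numbered arrays did not deviate together (correlations -0.103, -0.022 and 0.057, with 1 of 6 arrays correlating best with its own number). No pairing by number was seen, but so few arrays cannot exclude a small effect of a shared litter, day or batch.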

Other observations

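Gene families defined by symbol stem were examined after seeing the data, and 17 of 210 families with at least 8 genes differed from other genes by limma's camera (11 higher, 6 lower), of which 12 were called the same way with cyclic loess and 0 with an estimated correlation (adjusted p = 0.511 for each called family named here). A family held every gene whose symbol had the same letters before its first digit. The names of function used here may therefore not cover every member. Falls went beyond the cytochromes P450. Carboxylesterase genes (Ces), which hydrolyse drugs and lipids, fell for 8 of 9 members with a median of -1.40 (adjusted p = 0.000217), and glucuronosyltransferase genes (Ugt) for 7 of 9 with a median of -1.53 (adjusted p = 0.000413). Hydroxysteroid dehydrogenases (Hsd) fell for 11 of 17 members and rose for 1, and Serpina protease inhibitors fell for 7 of 8 (2 fell and 1 rose, with a median of -0.02, when arrays were scaled to the bacterial controls). Probes within these families can bind close relatives.

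Other families were called higher. Translation initiation factors (Eif) rose for 20 of 42 members with 0 lower and a median of 0.23 (adjusted p = 0.000413), though with cyclic loess 15 rose and 2 fell. Proteasome regulatory subunits (Psmd) rose for 11 of 14 (7 with cyclic loess) and chaperonin subunits (Cct) for 6 of 8 (6 with cyclic loess). Annexins (Anxa) rose for 7 of 11 with a median of 0.51 (6 with cyclic loess). Small ribosomal subunit genes of the cytosol (Rps, adjusted p = 0.0426) and mitochondria (Mrps, adjusted p = 0.0426) lost the call with cyclic loess (0.251 and 0.504), and the large subunit genes Rpl (0.0566) and Mrpl (0.0862) and the proteasome core genes Psma (0.0862) and Psmb (0.168) were not called. With arrays scaled to the bacterial controls, which moved the median of all genes to 0.34, the medians were 0.61 for Eif, 0.70 for Psmd, 0.80 for Cct and 0.89 for Anxa.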
